A study of Mus musculus with 4 samples.

How the data were processed

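Basal ganglia were dissected from CD1 mouse embryos at E13.5 and E16.5, cross-linked and sheared, and Sp9-bound DNA was isolated with a rabbit antibody to Sp9, per the labels' protocols. The series has 4 libraries: 1 Sp9 ChIP library and 1 input library per stage. Only the 2 ChIP libraries have a peak list used here, and the inputs entered only through the authors' peak calling, per the file names. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq 1.8.4, BWA 0.6.2, MACS2 2.1.0 and the mm9 build, without roles or settings; the peak threshold is not given in the sources used here. Per the file headers, the authors assigned each peak to genes whose regulatory domain reached it. A domain ran from 5000 bp upstream to 1000 bp downstream of the TSS and was extended up to 1000000 bp, with curated domains included.

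The deposited values are text of no standard unit, per the file headers: for each gene, the numbered peaks assigned to it and the signed distance of each from its TSS. They hold no peak height, width, coordinate, fold or q, so neither depth nor peak strength could be taken into account, and precision rests on the number of peaks alone. Some numbered peaks are divided into lettered entries (114 peaks at E13.5 and 163 at E16.5), all with the distance of the whole peak, so each number was counted as 1 peak. Numbers run to 5982 at E13.5 and 6130 at E16.5, and 135 and 108 of them (2.26% and 1.76%) are assigned to no listed gene. In the E13.5 list 69.4% of peaks are assigned to 2 genes, and in the E16.5 list 61.1%. Each list holds 2 mitochondrial peaks. A peak's position class was set by its nearest listed TSS.

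Gene names were matched to a table of mouse genes (assembly GRCm38.p6, another build than the lists', so used for names, synonyms and gene type only). Of 4826 names at E13.5, 4698 matched, 281 through a synonym, and of 5463 at E16.5, 5330 matched, 326 through a synonym. Of the unmatched names, 10 and 9 have the form of a calendar date, as spreadsheet programs write some gene names. All 21900 protein-coding genes of the table served as background, including those in neither list. Beyond 5 kb upstream and 1 kb downstream a peak is assigned only to the genes flanking it, so wider windows favour genes in gene-poor regions. The narrow window is complete for every gene of the authors' gene set and was run as an alternative. Background genes missing from that set, if any, could receive no peak in any window. They would lower the share of other genes with a peak, and their number was not known.

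The planned comparison of peak intervals could not be made without coordinates. In its place, peaks of the same gene with TSS distances within 200 bp were called recurring, which adapts a measure listed beforehand as an alternative. It was taken as the main measure only after the files, including the differences in distance between the lists, had been seen. Chance was estimated from 1000 seeded draws that shifted each gene's peaks of the other list by 1 to 50 kb in either direction. Promoters were defined as within 1 kb of a TSS. Shares carry 95% Wilson intervals. Groups were compared with Fisher's exact test, two-sided, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Analyses used Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

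The 18 gene lists, the 50 kb window, the tests and the rule for naming genes were fixed before the data were examined. The rule named Sp8, Sp9 and Six3 with every peak within 100 kb, up to 4 genes of each list, and the 5 genes with the most peaks within 50 kb in each list. The 4 genes per list were to be those of highest fold enrichment; without fold values, those with the most peaks within 50 kb over both lists were taken, ties going to the nearest. Other named genes, including Gad1, Bcl11b, Tle4, Gsx2, Drd1 and Drd2, farther peaks of Six3 and Sp8, and members near a peak at 1 stage only, were chosen after their values were seen. Single values of a few list genes are not reported here.

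The matching and list tests were tested on simulated data. With 0%, 30%, 60% and 90% of the 5847 E13.5 peaks kept within 100 bp of their place, 0.445%, 30.3%, 60.0% and 90.0% were found to recur. The remaining peaks were moved much farther than the 200 bp limit, so this outcome was built in. It checks the matching procedure, not how many shared sites were missed in these lists. With 200 simulated 14-gene lists per setting among 21900 genes, at the E13.5 rate, the list test called 1.5% at an odds ratio of 1, 61.5% at 5 and 100% at 20. These simulated calls used an unadjusted Fisher's exact p under 0.05. The real lists were judged after Benjamini-Hochberg adjustment, so the power of the test as applied was lower than these shares or at most equal. Alternatives tried were matching within 100 bp, 500 bp and 1 kb, promoters within 500 bp and 2.5 kb, windows of 10 and 100 kb, the narrow window and the nearest TSS. Further alternatives were a background without predicted genes and olfactory or vomeronasal receptors, lettered entries as peaks, lists without mitochondrial peaks or without any peak of the 28 genes that have a peak divided into 3 or more entries (leaving 5740 and 5937 peaks), list genes sharing a peak counted once, and only peaks whose nearest listed gene codes for protein. Not run, for lack of coordinates, sequence or peak scores, were motif searches, exon, intron and intergenic shares, interval overlaps and placement on chromosomes. The same holds for recurrence by fold enrichment, stricter thresholds on fold or q, top-ranked peaks, and removal of the Y chromosome and unplaced contigs.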

Results

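Sp9 is a zinc finger transcription factor of the SP/KLF family that is made in the developing ganglionic eminences and in young striatal neurons. Its binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in basal ganglia of wild-type CD1 mouse embryos at embryonic day 13.5 (E13.5) and embryonic day 16.5 (E16.5). Each stage had 1 Sp9 ChIP library, and 1 input library without antibody whose own signal was not analysed here. The deposited lists held 5847 peaks at E13.5 and 6022 peaks at E16.5, each given as a distance in base pairs from the transcription start site (TSS) of a named gene on the mouse mm9 build. They give no chromosome position, height, fold enrichment or read total, so sequencing depth was unknown. A gene absent from a list had no peak past the authors' threshold, which does not exclude weaker binding. With 1 library per stage there was no replicate check, and the p-values compare these lists, not the stages. Intervals cover counting error over peaks or genes only, and neighbouring peaks and genes are not independent replicates.

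The first question was where Sp9 peaks lay relative to genes at the 2 stages. At E13.5, 993 peaks (17.0%, 95% Wilson interval 16.04 to 17.97) lay within 1 kb of a TSS, here called promoter peaks. At E16.5 there were 1888 promoter peaks (31.4%, 30.2 to 32.5), 14.4 percentage points more, with an odds ratio of 2.23 (2.04 to 2.44; Fisher's exact test, two-sided, p = 2.28e-75). Peaks 50 to 500 kb from a TSS made up 49.6% of the E13.5 list and 39.1% of the E16.5 list, and the median distance to the nearest listed TSS was 68.6 kb at E13.5 and 32.1 kb at E16.5. Counted by gene, 1079 of 21900 protein-coding genes (4.93%) had a promoter peak at E13.5 and 2063 (9.42%) at E16.5. Both lists shared 744 of these genes, against 101.6 for independent lists of these sizes, while 335 genes had a promoter peak at E13.5 only and 1319 at E16.5 only.

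**Figure D1:**
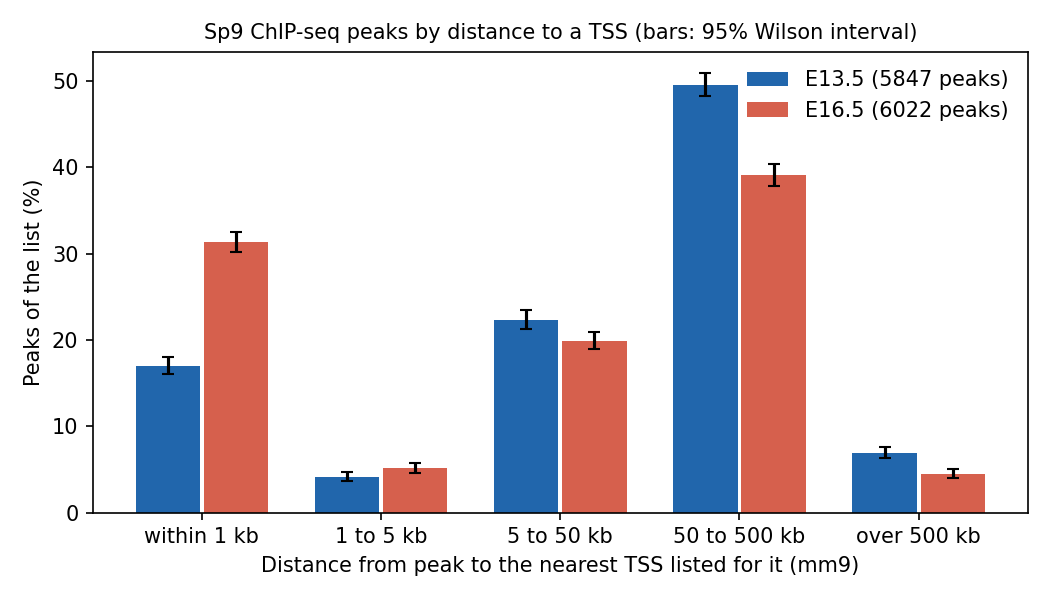
Share of each stage's Sp9 peaks (y axis, %) by distance to the nearest TSS listed for the peak (x axis), with 95% Wilson intervals as error bars. Promoter peaks made up 17.0% of the E13.5 list and 31.4% of the E16.5 list, and peaks 50 to 500 kb away 49.6% and 39.1%.

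The second question was how many sites recurred between the stages. A peak was counted as recurring when the other list had a peak of the same gene whose TSS distance differed by at most 200 bp. By this measure 3383 of the 5847 E13.5 peaks (57.9%, 56.6 to 59.1) and 3383 of the 6022 E16.5 peaks (56.2%, 54.9 to 57.4) recurred. When each gene's peaks were displaced by 1 to 50 kb at random, a mean of 22.5 E13.5 peaks matched and no draw gave more than 41 (one-sided permutation p = 0.001, the smallest that 1000 draws can give). Every shift exceeded the 200 bp limit, so pairs at the same place were always broken, and a low p was largely built in. The shifts also moved promoter peaks off the TSS. Any tendency of peaks in both lists to gather there was therefore not part of this chance estimate. At E13.5, promoter peaks recurred somewhat more often than peaks farther away (62.9% against 56.8%; Fisher's exact p = 0.000366). At E16.5 the order was the opposite: 628 of 1888 promoter peaks (33.3%) recurred against 66.6% of the peaks farther away (odds ratio 0.249, Fisher's exact p = 3.01e-130). The E13.5 list held only 993 promoter peaks, so many of the 1888 had no E13.5 peak of their own to match. That by itself lowers the E16.5 promoter share. Among peaks that did not recur, 14.9% at E13.5 and 47.7% at E16.5 were promoter peaks, whereas promoters held 18.5% and 18.6% of the recurring peaks.

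The study asked how Sp8 and Sp9 act on Six3 in the making of D2-type medium spiny neurons, the striatal projection neurons that carry the dopamine receptor Drd2. Six3, a homeodomain transcription factor, had 5 assigned peaks at E13.5 and 4 at E16.5. Peaks 226633 and 158325 bp upstream of the Six3 TSS at E13.5 recurred at 226673 and 158369 bp in the E16.5 list. Within 100 kb of Six3, the E13.5 list held a peak 92082 bp upstream, and the E16.5 list held one 91865 bp upstream and one 5 bp upstream of the TSS. The pair near 92 kb lay slightly too far apart to count as recurring, and the E13.5 list had no peak at the Six3 promoter. The other E13.5 peaks of Six3 lay 243398 and 112839 bp upstream.

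Sp9 peaks also lay at the genes of Sp9 and of its close paralogue Sp8. At the Sp9 gene, peaks 2918 bp upstream and 4564 and 7908 bp downstream of the TSS at E13.5 recurred at 2867, 4559 and 7882 bp in the E16.5 list. A further peak 127 bp upstream of the Sp9 TSS was in the E13.5 list only. At Sp8, the peak 9455 bp upstream at E13.5 recurred at 9442 bp in the E16.5 list, and within 100 kb the E13.5 list held 1 more peak, 61576 bp upstream. Farther from Sp8, peaks 186736 and 125987 bp upstream at E13.5 recurred at 186782 and 125957 bp. A peak 468499 bp upstream at E13.5 and peaks 374938 and 198413 bp upstream at E16.5 did not recur. The Sp8 peaks were all assigned to Sp4 as well. Those 468499 and 374938 bp from Sp8 lay nearer to Sp4, at 76390 and 169951 bp upstream of its TSS. Whether single peaks differed in strength between the stages could not be tested, because the lists give no heights.

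**Figure D2:**
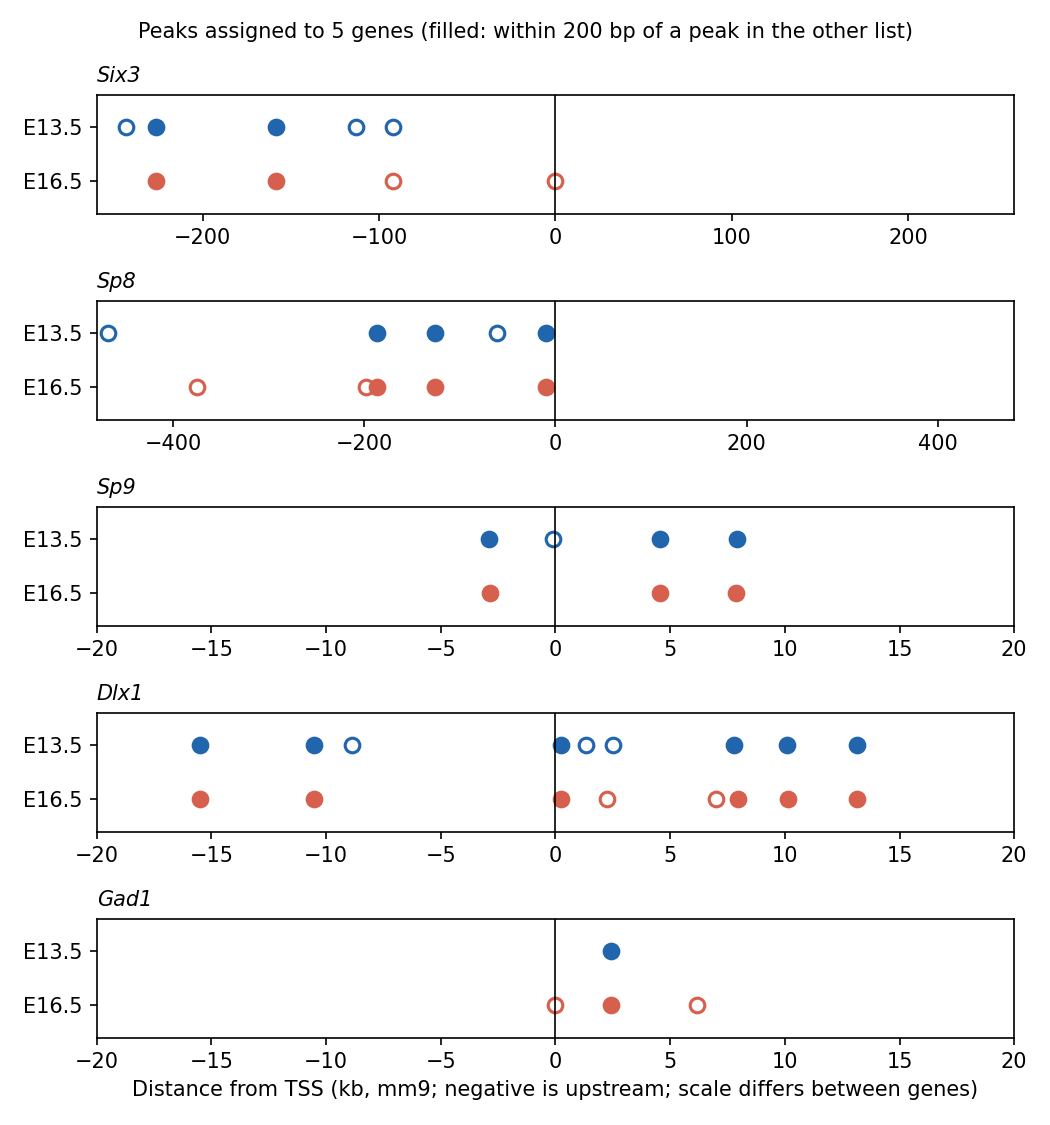
Sp9 peaks assigned to Six3, Sp8, Sp9, Dlx1 and Gad1, placed by distance from the TSS (x axis, kb on mm9, negative upstream, scale set per gene) for each stage (y axis). Filled points recurred within 200 bp and open points did not; the peak 5 bp upstream of Six3 stands in the E16.5 row only, and the peak 127 bp upstream of Sp9 in the E13.5 row only.

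The third question was which groups of genes had Sp9 peaks nearby. For 18 gene lists fixed before the data were examined, the share of genes with a peak within 50 kb of the TSS was compared with all other protein-coding genes, about 10.8% of which had such a peak at E13.5 and 15.0% at E16.5 (Fisher's exact test, two-sided, Benjamini-Hochberg over 36 tests). At E13.5, 6 lists were higher than other genes; at E16.5, 8 lists were. No list was lower at either stage, at an unadjusted p under 0.05 either. A list of 14 genes could not have been called lower, even with 0 genes near a peak. Such an outcome gave an unadjusted Fisher's exact p of 0.388 for liver and heart muscle at E13.5. For endothelium, microglia and blood at E16.5 it gave 0.250. The list of ventricular and subventricular zone regulators of the ganglionic eminence stood highest at E13.5, with 10 of 14 genes (71.4%, 45.4 to 88.3; adjusted Fisher's exact p = 2.56e-06). At E16.5 it had 9 of 14 genes (64.3%; adjusted Fisher's exact p = 0.000276).

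Among these regulators, 8 genes had a nearby peak at both stages. Dlx1 and Dlx2, adjacent homeobox genes that drive the differentiation of GABAergic neurons, had 9 and 7 peaks within 50 kb at E13.5 and 8 and 5 at E16.5, and the E13.5 peaks of the pair were 11 distinct peaks. The related pair Dlx5 and Dlx6 had 3 peaks each at both stages. Tle4, a corepressor gene, had nearby peaks at E13.5 and none at E16.5, and Gsx2, a homeobox gene of lateral ganglionic eminence progenitors, had one at E16.5 and none at E13.5. When genes sharing a peak were counted once, 8 of 12 regulators at E13.5 and 7 of 12 at E16.5 had a nearby peak (adjusted Fisher's exact p = 9.45e-05 and 0.00274).

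Genes of striatal neurons of both types were also higher than other genes, with 10 of 19 at E13.5 (adjusted Fisher's exact p = 9.45e-05) and 11 of 19 at E16.5 (0.000186). Meis2, a homeodomain factor of striatal neurons, had 4 peaks within 50 kb at E13.5 and 3 at E16.5, and the forkhead gene Foxp2 had 3 and 2. Pbx3 had 3 and 2, and Gad2, which encodes a GABA-synthesising enzyme, had 1 and 3. Gad1, the other such enzyme, had a peak 2428 bp from the TSS at E13.5 that recurred at 2401 bp, and a peak 40 bp from the TSS at E16.5 only. Bcl11b, a zinc finger factor required for medium spiny neuron maturation, had no peak within 50 kb at E13.5 and peaks at 4547 and 33506 bp at E16.5. Its 3 farther peaks, at 75165, 143653 and 195193 bp at E13.5, all recurred.

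The lists for D2-type and D1-type medium spiny neurons did not differ from other genes by this test at either stage. Of the D2 list, 3 of 11 genes at E13.5 and 4 of 11 at E16.5 had a peak within 50 kb (adjusted Fisher's exact p = 0.176 and 0.126), and of the D1 list 3 of 10 and 4 of 10 (0.145 and 0.0958). Sp9, the glutamate receptor subunit gene Grik3 and the delta opioid receptor gene Oprd1 were the D2 genes near a peak at both stages, and Six3 joined them at E16.5. The D1 genes at both stages were Zfp521, Isl1 and Ebf1, all transcriptional regulators, and the muscarinic receptor gene Chrm4 was added at E16.5. Isl1 had a peak 12626 bp downstream of its TSS at E13.5 that recurred at 12605 bp. Drd2 had a single peak, 67984 bp downstream, in the E16.5 list only. Drd1, the receptor that defines D1 neurons, had 4 peaks at E13.5, from 131515 to 523511 bp downstream, and all 4 recurred. Both lists passed when each peak was given to its nearest TSS at any distance (adjusted Fisher's exact p = 0.0264 for D2 and 0.0173 for D1 at E13.5, 0.0459 and 0.00719 at E16.5). The pallial and general neuronal lists passed there too, so this was not particular to D1 or D2 genes. In the window from 5 kb upstream to 1 kb downstream neither list passed. It held 1 of 11 D2 and 0 of 10 D1 genes at E13.5, and 3 of 11 and 1 of 10 at E16.5.

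Markers of neighbouring germinal zones and of migrating interneurons had nearby peaks as well. The medial ganglionic eminence list had 7 of 14 genes at E13.5 and 8 of 14 at E16.5 (adjusted Fisher's exact p = 0.00133 and 0.00134). Lhx6, a LIM homeodomain factor of cortical interneurons, had a peak 804 bp from its TSS at E13.5 that recurred at 972 bp, and Gbx2 and Zeb2 also had peaks within 50 kb at both stages. The list for the caudal and dorsal lateral eminence and olfactory bulb interneurons had 6 of 14 and 7 of 14 genes (0.00676 at both stages). It included Nr2f1, Npas1 and Th, which encodes the rate-limiting enzyme of dopamine synthesis, besides Sp8 and Sp9. In the window from 5 kb upstream to 1 kb downstream, chosen after the data were seen, the medial list lost its call at E16.5 (adjusted Fisher's exact p = 0.350), and the caudal and dorsal list at both stages (0.357 and 0.153).

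Genes for axon guidance had nearby peaks in 13 of 23 cases at E13.5 and 10 of 23 at E16.5 (adjusted Fisher's exact p = 2.56e-06 and 0.00368). Epha4, an ephrin receptor, had 4 peaks within 50 kb at E13.5 and 1 at E16.5, and the Slit receptor gene Robo1 had 2 and 3. Slit1 and Plxna2 had 2 each at both stages. Dcc, Plxna1 and Robo2 had a nearby peak at E13.5 only, and no listed gene at E16.5 only, a difference that did not pass correction (Fisher's exact p = 0.0252, adjusted p = 0.737). Few of these peaks were close to the promoter: in the window from 5 kb upstream to 1 kb downstream the list had 3 of 23 genes at each stage (adjusted Fisher's exact p = 0.336 and 0.790), and within 10 kb it passed at E13.5 (0.00235) and not at E16.5 (0.310).

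The SP/KLF family itself had nearby peaks in 9 of 21 genes at E13.5 and 11 of 21 at E16.5 (adjusted Fisher's exact p = 0.000893 and 0.000432). Sp4 had peaks 160 bp from its TSS at E13.5 and 173 bp at E16.5, and Klf7 at 673 and 357 bp. Klf10 had 1 nearby peak at E13.5 and 2 at E16.5. The 3 genes Sp8, Sp9 and Six3, chosen because the study is about them, passed at E16.5 with 3 of 3 (0.00945) and not at E13.5 with 2 of 3 (0.0732). In the window from 5 kb upstream to 1 kb downstream they did not pass at E16.5 either (0.113). They did pass at E13.5 within 10 kb (0.0347), within 100 kb (0.00803) and by nearest TSS at any distance (0.00719).

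Housekeeping genes had nearby peaks in 2 of 15 cases at E13.5 and 7 of 15 at E16.5 (adjusted Fisher's exact p = 0.734 and 0.00945). Polr2a, the largest RNA polymerase II subunit, and the ribosomal protein gene Rpl13a had promoter peaks at both stages. Sdha and the translation factor gene Eef1a1 had promoter peaks at E16.5 only, 77 and 114 bp from the TSS, as did Actb, Hsp90ab1 and Ywhaz. Compared with other genes that had a promoter peak at 1 stage only, the 0 against 5 housekeeping genes at E13.5 and E16.5 gave a Fisher's exact p of 0.590; with 5 genes, all at E16.5, no lower p was possible in this direction, so the test decides nothing. No list passed this test of the difference between stages within 1 kb or within 50 kb after correction over 36 tests.

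The other lists did not pass at either stage, although by nearest TSS at any distance the pallial and general neuronal lists passed at both stages (adjusted Fisher's exact p from 3.65e-05 to 0.0483) and the radial glia and Notch lists at E13.5 (0.0364 and 0.0150). Within 100 kb the radial glia list also passed at E13.5, with 5 of 12 genes (adjusted Fisher's exact p = 0.0438). The pallial glutamatergic lineage had 2 of 15 genes at E13.5 and 3 of 15 at E16.5, with Lhx2 and Bhlhe22 at both (adjusted Fisher's exact p = 0.734 and 0.582). General neuronal genes had 4 of 13 at both stages, namely Dcx, Elavl4, Tubb3 and Snap25 (0.0929 and 0.187). Radial glia had 3 of 12 at both stages, and Sox2, a neural stem cell factor, had 2 nearby peaks at E13.5 and 5 at E16.5 (0.199 and 0.505). Cell cycle genes had 3 of 13 and 2 of 13, with the cyclin-dependent kinase inhibitor gene Cdkn1b at both stages (0.225 and 1). Notch signalling genes had 5 of 17 at both stages, with Dll1, Notch1 and Mfng shared (0.0720 and 0.225). Of the lists for other cell types, the oligodendrocyte lineage had 3 of 8 (Olig1, Olig2 and Pdgfra) and 1 of 8 (Sox10), with adjusted p of 0.0932 and 1. Endothelium, microglia and blood had 2 of 14 (Cdh5 and Ptprc) and 0 of 14 (0.734 and 0.333). Liver and heart muscle had 0 of 14 and 2 of 14 (Fga and Fgb), with adjusted p of 0.499 and 1.

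**Figure D3:**
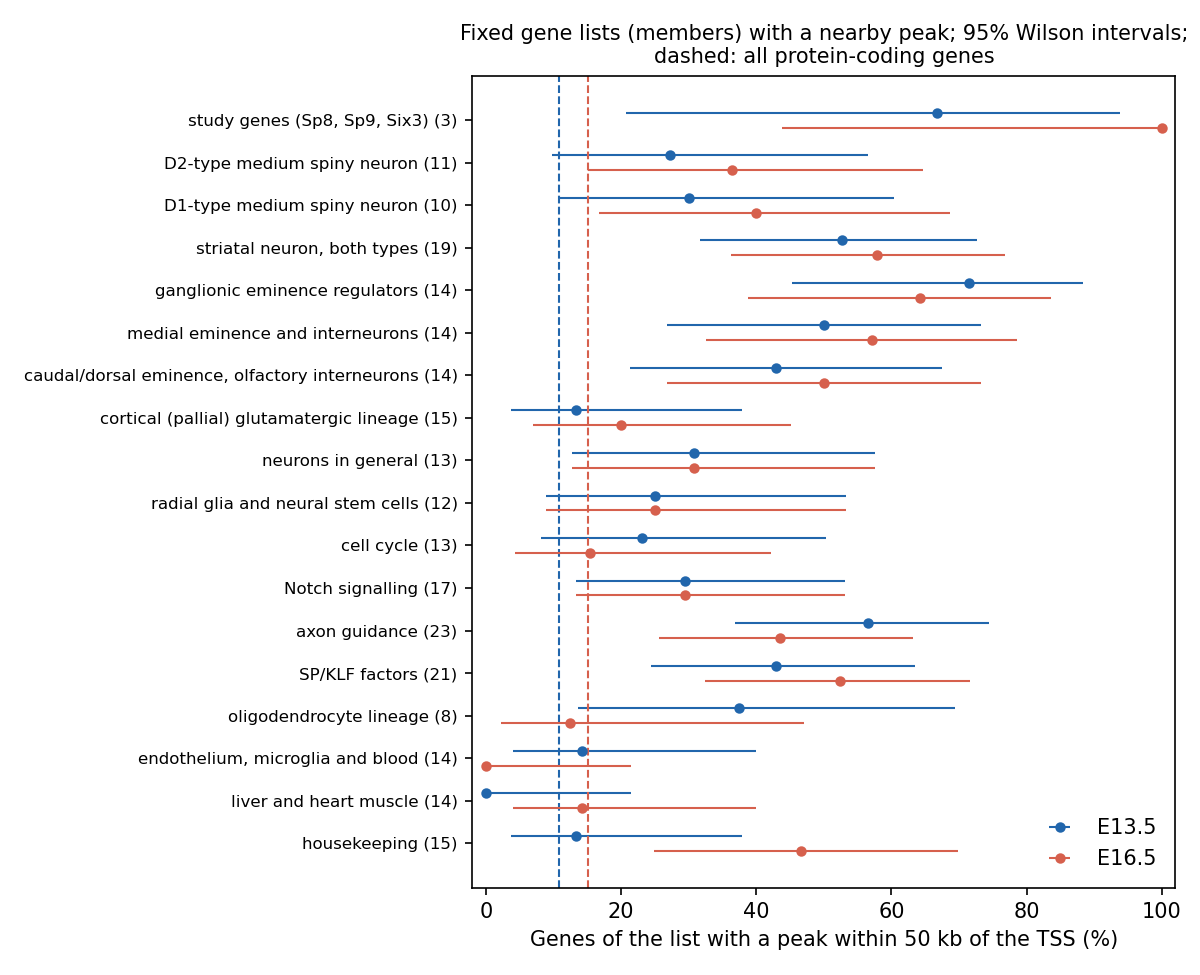
Share of each fixed gene list (y axis, number of genes in parentheses) with an Sp9 peak within 50 kb of the TSS (x axis, %), with 95% Wilson intervals; dashed lines mark all protein-coding genes at each stage. Ganglionic eminence regulators stood at 71.4% at E13.5 and 64.3% at E16.5.

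Apart from Dlx1 and Dlx2, the genes with the most peaks within 50 kb were in none of these lists. With each peak number counted once, the leading genes at E13.5 were Cwc22, which encodes a spliceosome-associated protein, with 36 peaks, the predicted gene Gm10718 with 12, and Dlx1 with 9. Dlx2, 3110070M22Rik, Gm9874 and Gse1 followed with 7 each. At E16.5 the leading genes were Itln1, a lectin gene, with 15 peaks, 1600014C10Rik with 13, the immune receptor gene Cd244 with 12, and Gm10718 and Mroh2a with 11 each. Of these peaks, 6 of 9 recurred at Dlx1 and 11 of 12 at Gm10718 in the E13.5 list, and 1 of 36 at Cwc22, where the E16.5 list held 8 peaks within 50 kb. Some peak numbers were divided into lettered entries, and by entries Cwc22 had 103 at E13.5 and 107 at E16.5 within 50 kb, so its fall from 36 to 8 and its place at E16.5 depend on counting each number once. In the E16.5 list 1 of 15 recurred at Itln1, 1 of 12 at Cd244 and 0 of 11 at Mroh2a, where the E13.5 list held 5, 5 and 0 peaks within 50 kb, so few or none could recur. The 13 peaks of 1600014C10Rik at E16.5 were also divided, into 26 entries. A peak can be assigned to 2 genes, so counts of neighbouring genes may share peaks. The inputs' own signal was not analysed, so whether these clusters, recurring or not, were Sp9 sites was not tested.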

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

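Of the tests in this part, those on distant peaks and on housekeeping genes were chosen only after the results were seen, as was the comparison of peaks that occur in 1 list only; those on divided and mitochondrial peaks and on recurrence at Cwc22 were written before their results.

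Among peaks in 1 list only, promoter peaks were more frequent at E16.5 than at E13.5 (odds ratio 5.20, Fisher's exact p = 2.55e-145). This marked them as a difference between the lists. It largely restates the promoter excess given above, since the recurring promoter peaks were nearly equal in number (625 at E13.5 and 628 at E16.5). A more sensitive E16.5 library or looser threshold, adding peaks at every distance, would leave at least as many beyond 1 kb. The ratio of E16.5 to E13.5 was 0.852 (0.817 to 0.888), which argues against such an addition as the whole cause. This ratio follows from the list sizes (5847 and 6022) and the promoter counts already given, so it is not independent evidence. Heavily divided and mitochondrial peaks are not the cause either, since the odds ratio for all promoter peaks was 2.23 with all peaks and 2.24 (2.05 to 2.44) without any peak of the 28 genes that have a peak divided into 3 or more entries, mitochondrial genes among them. A general signal at active promoters in the E16.5 library could not be tested with the housekeeping genes fixed beforehand. They had such peaks at E16.5 only in 5 cases and at E13.5 only in 0. That is the most extreme outcome possible for them, and it still gives a Fisher's exact p of 0.590. A pooled set of 303 ribosomal, translation, splicing and proteasome genes was also chosen after the results were seen. It had 45 genes at E16.5 only and 4 at E13.5 only, against 1274 and 331 other genes (odds ratio 2.92, Fisher's exact p = 0.0301). This is the direction that a general promoter signal would give. That explanation and a change in Sp9 binding with embryonic age cannot be told apart with 1 library per stage.

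At E16.5 a single numbered peak whose nearest gene was Cwc22 was divided into 58 lettered entries, a signal outside the comparisons above, which count each number once. Around Cwc22 (within 100 kb), 5 of 52 E13.5 peaks recurred within 200 bp (9.62%, 4.18 to 20.6), against 58.3% of all other E13.5 peaks and 54.5% (6 of 11) of those near Dlx1 or Dlx2. The E16.5 list held only 15 numbered peaks there, of which 5 recurred, so at most 28.8% of the E13.5 peaks could have matched a peak of their own, and these shares decide nothing. Extra copies of this segment in CD1 mice or a repeat collapsed in the reference, giving broad enrichment, are 1 explanation. Discrete recurring Sp9 sites within the divided peaks are another, and recurrence therefore cannot tell them apart. Divided peaks were 31 of the 52 at Cwc22 at E13.5 (59.6%), against 1.43% of all other E13.5 peaks. Near Dlx1 or Dlx2 they were 0 of 11, so in this respect the cluster was unlike those sites. Cwc22 lies in a region whose copy number is known to vary among mice. Both stages used CD1 embryos, so no biological explanation was tested.

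At E13.5 the most divided peak, with 29 lettered entries, had Sfi1 as its nearest gene. Both genes had heavily divided peaks at both stages. Sfi1 was nearest to E16.5 peaks of 54 and 20 entries, and Cwc22 to E13.5 peaks of up to 10.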

How the results depend on the processing

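The matching distances of 100 and 500 bp, the promoter limit of 500 bp, the window from 5 kb upstream to 1 kb downstream, and the alternatives on divided, mitochondrial, lettered, coding and shared peaks were chosen after seeing the data; the others were planned. Of 54 alternatives for the 9 results on peak numbers, recurrence, promoter share and list counts, 52 kept their direction and side of the threshold or stayed within 1.5 times. This is a weak check, since many of them could hardly change. No list was lower than other genes in any setting, and the recurrence p was the smallest possible throughout. Within the limit of 1.5 times, fewer lists were higher at E13.5 in the narrow window, and more at E16.5 by nearest TSS. Recurrence ranged from 49.96% (within 100 bp) to 61.2% (within 1 kb) of E13.5 peaks and from 48.5% to 59.3% of E16.5 peaks, and the promoter difference from 13.3 to 15.0 percentage points. The number of lists higher than other genes moved from 6 to 13 at E13.5 when each peak went to its nearest TSS at any distance, and from 8 to 4 at E16.5 in the window from 5 kb upstream to 1 kb downstream; the cause was not tested. For single lists, 247 of 288 alternatives kept direction and side, 14 passed the threshold only in the alternative, 7 only in the main window, and 20 changed direction, all in lists that passed in neither setting. The differences from other genes that changed direction, in percentage points, were in the narrow window at E13.5 -5.51 for D1 neurons, radial glia, oligodendrocytes and blood or endothelium, and at E16.5 -0.196 for D1 neurons, -3.53 for pallial, -1.86 for radial glia, -2.51 for cell cycle and -4.32 for Notch genes. Within 10 kb they were -6.62 for oligodendrocytes at E13.5 and -1.21 for D1 neurons and -3.52 for cell cycle genes at E16.5. Within 100 kb they were -0.932 for housekeeping genes at E13.5 and -2.52 for cell cycle and 7.10 for oligodendrocyte genes at E16.5. By nearest TSS they were -0.450 for blood or endothelium and -1.40 for housekeeping genes at E13.5 and 7.57 for oligodendrocyte genes at E16.5. Cell cycle genes at E16.5 also stood at -1.91 with the reduced background. Without any peak of the 28 genes that have a heavily divided peak, they stood at -7.30. In that setting Ccne1, which has a peak of 3 entries at E16.5, lost its only nearby peak, 22488 bp from the TSS. The cause of the other changes was not tested, and lists of 8 to 17 genes shift with 1 or 2 members. Alternatives that need coordinates, sequence, fold or q (interval overlap, chromosome placement, stricter thresholds, top-ranked peaks, whole-interval positions, motif settings and removal of Y and unplaced contigs) were not run. Depth was unknown, so how far either list was limited by sequencing could not be assessed.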

Other observations

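The test of assignment domains and the gene families in this part were chosen after the results were seen; the test of recurrence near the regulators at E13.5 was written before its result, and the E16.5 values were added after it.

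With each peak number counted once and apart from Cwc22 (57 peaks at E13.5 and 22 at E16.5), the gene with the most assigned peaks at any distance was Zfp608 at both stages. By lettered entries the order differs: Cwc22 had 152 at E13.5 and 166 at E16.5, Zfp385b 91 and 95, Ube2e3 56 and 66, and Zfp608 32 and 25. No group of genes was tested here, and the other genes named were chosen after their counts were seen. Zfp608, a zinc finger gene, had 32 peaks at E13.5 and 24 at E16.5, of which 20 recurred. Auts2, a gene linked to autism and neurodevelopmental disorders, had 20 and 15 with 11 recurring, all of them more than 50 kb from the TSS. Sox2 had 18 and 17 with 10 recurring, and Meis2 13 and 11 with 6 recurring. The corepressor gene Tle4 had 13 and 11 with 8 recurring. The guidance receptor genes Robo1, Robo2, Dcc and Epha4 had 15, 14, 15 and 14 peaks at E13.5 and 10, 4, 8 and 7 at E16.5. Such counts grow with the size of a gene's assignment domain.

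Among 13 gene families defined by symbol, promoters of cytoplasmic ribosomal protein genes had a peak at E16.5 in 19 of 84 cases, more than other genes (adjusted Fisher's exact p = 0.00257), and in 6 of 84 at E13.5 (0.423). Within 50 kb at E16.5 this family also passed, with 23 of 84 (0.0154). Splicing factor genes had promoter peaks in 12 of 45 cases (0.00615) and proteasome genes in 9 of 40 (0.0462) at E16.5, and in 4 of 45 (0.397) and 4 of 40 (0.276) at E13.5; within 50 kb at E16.5 neither passed (0.112 and 0.321). Mitochondrial ribosomal protein genes with 14 of 78 and translation initiation genes with 10 of 56 promoters at E16.5 did not pass (0.0607 and 0.112). SOX and forkhead genes did not pass at promoters at either stage (0.367 and 0.316 at E13.5, 0.210 and 0.150 at E16.5). Within 50 kb they had peaks in 7 of 19 and 12 of 44 cases at E13.5 (0.0138 and 0.0119), and in 7 of 19 and 13 of 44 at E16.5 (0.0607 for both). Olfactory receptor genes had 0 of 1106 promoters with a peak at either stage. Protocadherin promoters had 0 of 69 and potassium channel subunit promoters 1 of 94 at both stages, lower than other genes at E16.5 (0.0119 for both) and not past the threshold at E13.5 (0.131 and 0.209) or within 50 kb at E16.5 (0.316 and 0.114). No single family differed between the stages after correction. Pooled, the ribosomal, translation, splicing and proteasome genes had a promoter peak at E16.5 only in 45 cases and at E13.5 only in 4. Against other genes this gave an unadjusted Fisher's exact p of 0.0301.

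Larger assignment domains in gene-poor regions could raise the share of ganglionic eminence regulators with a nearby peak. In the window from 5 kb upstream to 1 kb downstream, which every gene of the authors' gene set has in full, 7 of 14 regulators had a peak at E13.5 (odds ratio 17.2, Fisher's exact p = 3.7e-06) and 6 of 14 at E16.5 (odds ratio 6.62, Fisher's exact p = 0.00163), which argues against domain size as the whole cause. Background genes missing from that set, if any, would raise these odds ratios. A hypothesis that Sp9 sites near these regulators recur more often than other sites stayed open: 60.9% of the 23 E13.5 peaks near them recurred against 57.8% of the others (Fisher's exact p = 0.835), and 70.0% of the 20 E16.5 peaks against 56.1% (p = 0.262), differences that so few peaks cannot resolve.

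The peaks at Six3 and Sp9 promoters went opposite ways, with the Six3 promoter peak in the E16.5 list only and the Sp9 promoter peak in the E13.5 list only. Neither difference was tested, since the lists give no peak heights. Over all protein-coding genes, 1319 had a promoter peak at E16.5 only and 335 at E13.5 only, so the pattern at Six3 was the commoner.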
